A study of Mus musculus with 7 samples.

How the data were processed

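Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in CD15-positive neural progenitors sorted from the dorsal telencephalon of CD-1 mouse embryos at E14.5. The 7 libraries fall into 3 wild-type and 4 L3mbtl3 knockout libraries by the genotype given in the labels, where the study's design text calls the former control. The labels' growth protocol, worded alike for all libraries, also mentions heterozygous cells, and no library is labelled heterozygous. Libraries were made with a Nextera kit, per the labels' protocols. The submitters' processing notes name genome build GRCm38, CASAVA 1.9, FastQC 0.11.8, Bowtie2 2.3.5.1, SAMtools 1.9, deepTools 3.3.0 and MACS2. Their order, their settings, the MACS2 version and any shift of reads for the transposase are not given in the sources used here.

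The authors deposited 1 list of broad peaks per library, so peaks were called separately in each library and the library is the replicate. Each peak carries the authors' fold enrichment, a ratio over the peak caller's background. Each peak also carries a deposited −log10 p and −log10 q, and the smallest −log10 q lay between 1.30 and 1.32 in the 7 lists, so that the lists hold peaks with q up to about 0.05. The deposited score of each peak, a whole number, was not used. Fold and q are each list's own values and served only to rank or filter peaks within a list. The lists hold no read counts, so the sequencing depth of each library is unknown and no counting interval could be set on a single peak. The lists held 3366 to 17362 peaks, and a longer list can come from more reads, from a better signal over background or from more open chromatin. All peaks lay on chromosomes 1 to 19, X and Y.

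The peaks of all libraries were merged into regions where they overlapped by at least 1 bp, and a region was called in a library that had a peak in it. Gene positions came from a RefSeq gene table of GRCm38.p6 with 21883 protein-coding genes, which gives the start and end of each gene but no strand and no transcripts. Transcript starts, planned before the data were examined, were therefore replaced by both ends of the gene span, and a gene was called where a peak lay within 1 kb of either end. Regions were assigned to the nearest protein-coding gene span for the same reason. Shares in exons and introns and the density of proneural E-box motifs were also planned and were not run, since no transcript models and no genome sequence were used here. A peak near an end of 2 neighbouring genes counted for both. Coordinates are on GRCm38 and counted from 1.

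Values per library were compared between genotypes with a two-sided exact permutation test of the difference of means over all 35 splits of the 7 libraries into 3 and 4, for which the smallest p is 0.0286. Single regions were compared with Fisher's exact test, which has the same smallest p, so that no region can pass a Benjamini-Hochberg adjustment over all regions. The number of regions called in every library of 1 genotype and in none of the other was set against the same count in all 35 splits. After the counts per split were seen, an expected count was added from a model in which each library has its own odds of calling a region, fitted on the regions as a whole. On simulated lists for 25618 regions with 200 changed regions per direction, called with a probability of 90% in 1 genotype and 5% in the other, the ratio of observed to expected was 4.68 for wild-type and 5.42 for knockout and ranked first among the splits in 20 of 20 runs. With 50 changed regions the mean ratio was 1.89 ± 0.148 and 2.17 ± 0.292 (SD, 20 runs) and ranked first in 10 and 11 of 20 runs. With none the mean ratio was 0.959 and 1.04. Changed regions had the same probabilities in every library, whereas the fitted odds of calling ran from 1 to 33.0 relative to the lowest library. The simulation may therefore overstate what these lists could detect.

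The 16 gene lists were fixed before the data were examined and all of their 259 entries were found in the gene table. The share of each list called at a gene end was tested with the exact permutation test and adjusted over the lists by the Benjamini-Hochberg method. Peaks in the gene span and 50 kb on either side were also compared with 10000 random lists of protein-coding genes matched on deciles of gene length, a permutation of list membership added after the data were seen. Overlap between libraries was the Jaccard index, base pairs shared over base pairs in the union. The share of peaks at gene ends was compared with 100 random placements of the same peaks on their chromosomes, from 3 Mb onward.

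The genes named were chosen by a rule written before the data were examined. It takes L3mbtl3, up to 3 members per list with the largest difference between the shares of knockout and wild-type libraries calling them, and up to 10 genes per direction from the regions and gene ends called in every library of 1 genotype and none of the other. These are ranked by their mean percentile of −log10 q within the calling lists, and where a direction held fewer than 5, those with at most 1 library of the other genotype were added. Other genes are marked as chosen after their values were seen. Some genes that the rule takes are not reported here. Alternatives were peaks with −log10 q of at least 5, equal lists made of the 3366 highest-ranked peaks of every library, autosomes only, windows of 2.5 kb, other rules for merging and calling, leaving out each library, and pairing by replicate number. The labels do not say whether the libraries came from separate embryos or litters, so the p-values measure only the spread between these libraries, which may be technical. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.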

Results

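Open chromatin was profiled in CD15-positive neural progenitors of the dorsal telencephalon at E14.5, in 3 wild-type and 4 L3mbtl3 knockout libraries. E14.5 is the embryonic day, in mid-neurogenesis, and CD15 is a surface carbohydrate carried by neural stem and progenitor cells. L3mbtl3 encodes a protein with malignant brain tumour (MBT) domains that the study links to Polycomb repressive complex 1 (PRC1). The 3 wild-type lists held 7448, 11394 and 6458 peaks and the 4 knockout lists 9827, 7111, 3366 and 17362. The 62966 peaks merged into 25618 regions. The read depth behind the lists is unknown.

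At L3mbtl3 itself (chromosome 10, 26274461 to 26376036), no library of either genotype had a peak within 1 kb of an end of the gene. Inside the gene span, knockout library 4 had a peak at 26297303 to 26297408 and wild-type library 1 had a peak at 26327900 to 26328106. Neither position was called in any other library. These calls do not test whether the allele was deleted.

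The first comparison asks whether loss of L3mbtl3 was accompanied by a different amount of open chromatin. Wild-type lists averaged 8433 ± 2611 peaks (SD, n = 3) and knockout lists 9417 ± 5922 (SD, n = 4), a difference of 983 peaks that was smaller than the spread within either genotype (exact permutation p = 0.80). The lists covered 1704 ± 634 kb in wild-type and 1927 ± 1267 kb in knockout libraries (SD, n = 3 and 4, exact permutation p = 0.857). Median peak width was 160 ± 16.1 bp and 160 ± 13.4 bp (SD, n = 3 and 4, exact permutation p = 1).

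Peaks lay at gene ends more often than randomly placed peaks in both genotypes. Of all peaks, 18.99% ± 0.313 in wild-type and 18.3% ± 1.78 in knockout libraries (SD, n = 3 and 4) were within 1 kb of an end of a protein-coding gene, a difference of −0.730 percentage points (exact permutation p = 0.486). The same peaks placed at random gave 3.29% and 3.27%, so that the 7 lists held 5.05 to 6.06 times the random share at gene ends. Gene spans held 46.7% ± 0.172 of wild-type and 46.9% ± 2.53 of knockout peaks (SD, exact permutation p = 0.886), shares that were not compared with random placement. A peak at an end was found for 1836 ± 527 genes per wild-type and 1993 ± 1379 per knockout library (SD, n = 3 and 4, exact permutation p = 0.914). Peaks on chromosome Y numbered 1 to 15 per library (exact permutation p = 0.971). With Benjamini-Hochberg adjustment over the 7 comparisons of this kind every p was 1. The direction of the peak number depended on single libraries, at −4.5 peaks without wild-type library 3 and −1665 without knockout library 4, and the difference in genes was −35.8 and −492 without them and −13.3 with equal lists.

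**Figure D1:**
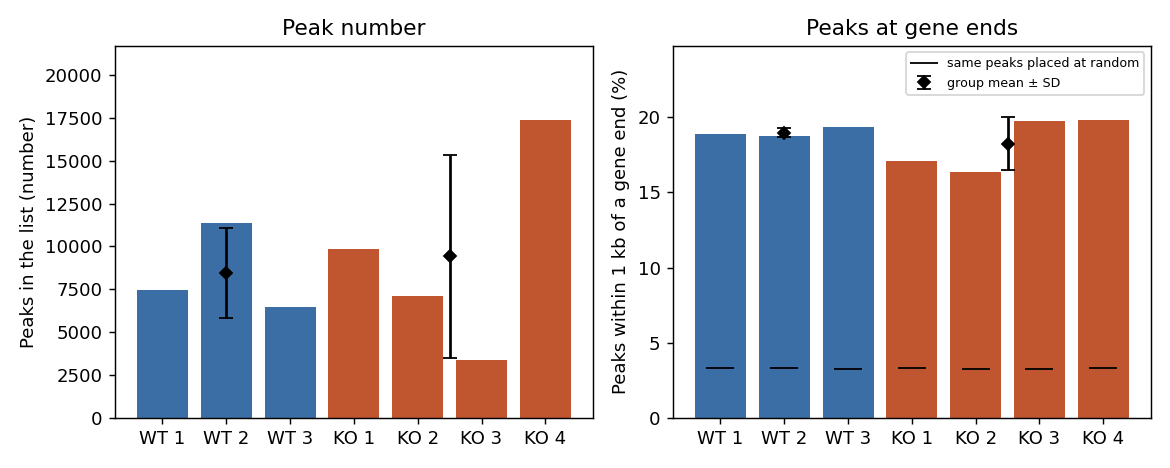
Number of peaks per library (left axis, peaks) and percent of peaks within 1 kb of a gene end (right axis) for the wild-type (WT, blue) and knockout (KO, orange) libraries, with group means ± SD as diamonds and the share after random placement as short lines. Knockout library 3 had the shortest list, 3366 peaks, and knockout library 4 the longest, 17362, while the share at gene ends lay between 16.4% and 19.8% in all 7.

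The second comparison asks which regions were open in 1 genotype and not in the other. Regions called in all 3 wild-type and no knockout library numbered 34, and regions called in all 4 knockout and no wild-type library numbered 28. The wild-type regions included 1 at the end of Siah3 (chromosome 14, 75454905 to 75455133), 1 inside Pitrm1, which encodes a mitochondrial peptidase (chromosome 13, 6557961 to 6558176), and 1 inside Csmd1 (chromosome 8, 17095780 to 17096178). The knockout regions included 1 inside Syt1, the calcium sensor of synaptic vesicle release (chromosome 10, 108769443 to 108769645), 1 inside the zinc-finger gene Zbtb20 (chromosome 16, 42921506 to 42921804) and 1 inside Sema5a, a semaphorin of axon guidance (chromosome 15, 32259544 to 32260056). None of these genes is in a fixed list of neural or Polycomb genes.

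Of the 10 wild-type regions with the highest mean −log10 q percentile, the others were at Gm4724 (chromosome 2, 175703695 to 175703830) and Slf1 (chromosome 13, 77048596 to 77048816), or lay between genes with Lce1i, the cytokine gene Il21, the histone demethylase gene Kdm4c, the adhesion gene Mdga2 or Cavin2 as the nearest. The distance to the nearest gene was 396040 bp at Kdm4c and 395841 bp at Mdga2. Of the 10 highest knockout regions, the others were at Ankrd42 (chromosome 7, 92637073 to 92637249), Arl16 (chromosome 11, 120467416 to 120467578), Lpp (chromosome 16, 24909020 to 24909170) and Dlgap1, a postsynaptic scaffold gene (chromosome 17, 70429847 to 70429985), or lay between genes nearest to the activin receptor gene Acvr2a, Zfp217 or Rapgef2. In all, 16 of the 34 wild-type and 20 of the 28 knockout regions touched a gene span, and 4 and 5 lay within 1 kb of a gene end.

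Each of these 62 regions had a Fisher exact p of 0.0286, the smallest the design allows, and no region passed the Benjamini-Hochberg adjustment. Among the 35 splits of the 7 libraries, 20 gave at least 34 regions in the group of 3 and 17 gave at least 28 in the group of 4, with the highest other counts at 446 and 349. Given each library's odds of calling a region, 29.8 and 22.2 regions were expected. The ratios were therefore 1.14 (95% interval 0.791 to 1.60) and 1.26 (0.836 to 1.82), intervals that cover counting error only. Ratios at least as high came from 15 of the 35 splits in the group of 3 and from 5 in the group of 4. With equal lists 0 of the 34 and 1 of the 28 regions remained separated. Equal lists drop the lower-ranked peaks of all but the shortest list. The median of the regions' mean −log10 q percentiles was 43.5 in wild-type and 50.5 in knockout. Most would therefore drop out whatever their cause, and this setting cannot decide on stability. The regions that remained numbered 18 and 10 where peaks had to cover at least 50% of the region, and 33 and 28 with peaks merged within 500 bp. Leaving out single libraries moved the counts to between 38 and 199 regions in wild-type and between 35 and 208 in knockout libraries, the highest without wild-type library 3 and without knockout library 3.

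**Figure D2:**
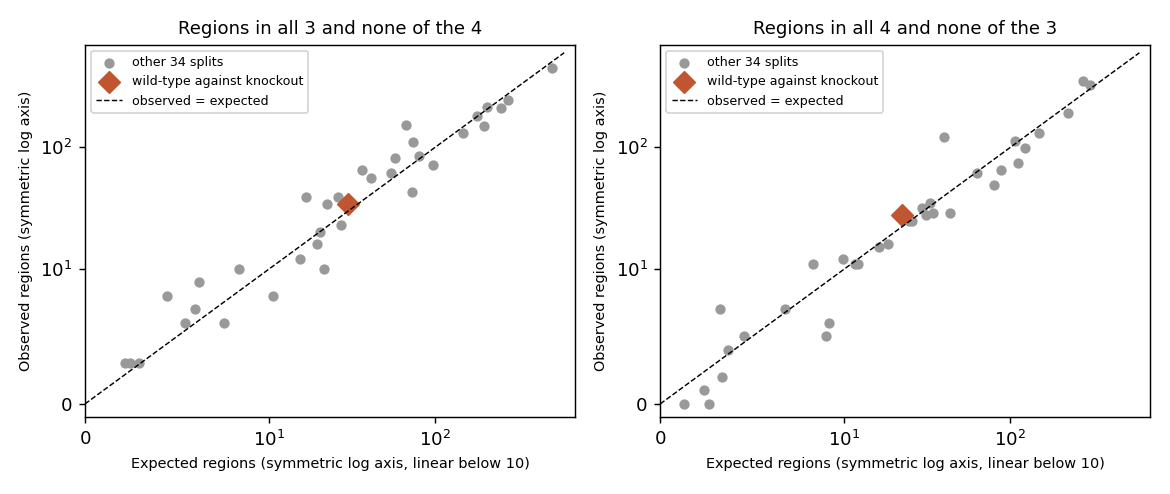
Observed against expected number of regions called in every library of 1 group and none of the other for all 35 splits of the 7 libraries, for the group of 3 (left) and the group of 4 (right), on axes that are linear below 10 and logarithmic above, with the dashed line where both are equal. The wild-type against knockout split (diamond) has 34 regions against 29.8 expected and 28 against 22.2, within the range of the other 34 splits (circles).

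Of the 25618 regions, 12388 (48.4%) were called in 1 library only, 6472 of them in knockout library 4, and 1296 (5.06%) were called in all 7. Median length was 123 bp for regions called in 1 library and 400 bp for those called in all 7. Merging extends a region over all of its peaks, so length grows with the number of callers by construction. Regions called in all 7 libraries included 1 beside Fezf2, a transcription factor gene of deep-layer cortical neurons (chromosome 14, 12337805 to 12338678), and 1 inside Gli3, a transcription factor gene of the hedgehog pathway (chromosome 13, 15543732 to 15544128). Peaks joined in a region need not all overlap each other. At Fezf2 the peak of wild-type library 3 did not overlap those of wild-type libraries 1 and 2. At Gli3 the peak of knockout library 2 did not overlap that of wild-type library 1.

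The third comparison concerns single genes with a peak at an end. Rbbp7, which encodes a histone-binding protein found in Polycomb repressive complex 2 (PRC2) and other chromatin complexes, had an end peak in 3 of 3 wild-type and 0 of 4 knockout libraries (region at chromosome X, 162760135 to 162760401, overlapping the lower end of the gene). Gm4724, Siah3 and Mageh1 had the same pattern. Rbbp7 and Mageh1 lie on chromosome X, and the sex of the embryos was not taken into account. Ankrd42 and Tmem243 were called in 0 of 3 wild-type and 4 of 4 knockout libraries. So were Arl16 and Hgs, an endosomal sorting gene, which share a peak, and Aif1l and the nuclear pore gene Nup214, which share another, so that either neighbour may be the gene concerned.

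Called in all 3 wild-type and in 1 of 4 knockout libraries were Isoc2b, the transcription factor gene Klf5, the collagen gene Col11a1, Trmt9b, Hpf1 and Inka2, which were added because fewer than 5 genes separated in this direction. At least 1 library called 5167 of the 21883 genes, and all 7 called 248. The 4 wild-type genes were matched or exceeded in 23 of the 35 splits and the 6 knockout genes in 20, with highest other counts of 120 and 82. With equal lists Rbbp7 was called in 1 of 3 wild-type and 0 of 4 knockout libraries, while Ankrd42 stayed at 0 of 3 and 4 of 4. Their mean −log10 q percentiles were 44.0 and 77.3, and equal lists drop lower-ranked peaks whatever their cause.

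**Figure D3:**
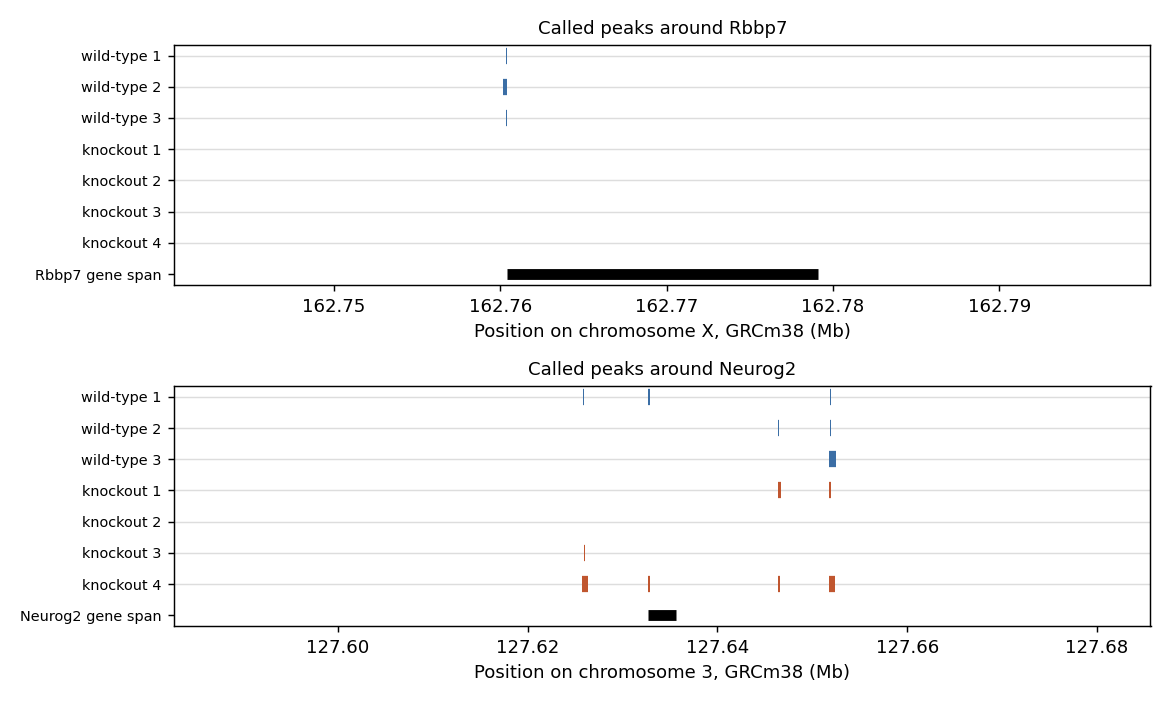
Called peaks in each library around Rbbp7 (top, chromosome X) and the proneural gene Neurog2 (bottom, chromosome 3), with position in Mb on GRCm38, wild-type peaks in blue, knockout peaks in orange and the gene span in black. The peak at Rbbp7 is in all 3 wild-type and no knockout libraries, and the region from 127651780 to 127652483 beside Neurog2 is in all 3 wild-type libraries and in knockout libraries 1 and 4.

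The fourth comparison asks whether genes of neurogenesis, of Polycomb complexes or of other cell types were opened or closed at their ends, the question the series title raises for proneural genes. Proneural and neurogenic bHLH genes, which drive progenitors toward neurons, had an end peak in 6.67% of 15 members in every wild-type library and in 11.7% ± 11.4 in knockout libraries (SD, n = 4). Neurod1 and Hes6 were each called in 0 of 3 wild-type and 1 of 4 knockout libraries, and Neurog2 in 1 of 3 and 1 of 4. Of the 15 members 4 were called in a larger share of knockout libraries, 2 in a larger share of wild-type libraries and 9 in none. The difference of 5 percentage points was within the spread between libraries (exact permutation p = 0.714, adjusted p = 1), and without knockout library 4, at 26.7%, it was 0. Counting a peak anywhere in the gene span and 50 kb on either side, it was 21.7 points (exact permutation p = 0.143). With windows of 2.5 kb it was −2.22 points.

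Radial glia and neural stem cell genes were called at 5% ± 5 in wild-type and 8.75% ± 4.79 in knockout libraries (SD, n = 3 and 4). Emx2, a patterning gene of the cortex, was called in 0 of 3 and 2 of 4 libraries, and Slc1a3, an astroglial glutamate transporter, and Gli3 each in 1 of 3 and 0 of 4. Excitatory neuron genes were called at 5.56% in every wild-type library and 11.1% ± 7.86 in knockout libraries (SD, n = 4), with Fezf2 in 2 of 3 and 4 of 4 (3 of 3 and 4 of 4 with a window of 2.5 kb) and Tubb3 and Dcx, both of the neuronal cytoskeleton, in 0 of 3 and 1 of 4. Intermediate progenitor genes were called at 2.78% ± 4.81 and 4.17% ± 8.33 (SD), with Tmem158 in 0 of 3 and 1 of 4, and no library called Eomes. Notch pathway genes were called at 11.1% ± 3.85 and 13.3% ± 5.44 (SD), with the coactivator gene Maml1 in 3 of 3 and 3 of 4 and Jag1 and Hes5 in 0 of 3 and 1 of 4. Without knockout library 4 the difference in percentage points was 1.67 for radial glia, 1.85 for excitatory neuron, −2.78 for intermediate progenitor and 0 for Notch pathway genes.

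PRC2 genes were called at 15.2% ± 5.25 in wild-type and 4.55% ± 9.09 in knockout libraries (SD, n = 3 and 4), a difference of −10.6 percentage points (exact permutation p = 0.229, adjusted p = 1). It was −1.52 on autosomes only, which leaves out the X-linked Rbbp7, −3.03 with equal lists, 0 at −log10 q of at least 5 and −15.2 without knockout library 4 (exact permutation p = 0.1). Of its 11 members, Rbbp7 was called in 3 of 3 and 0 of 4 libraries, Rbbp4 and Mtf2 were each called in 1 of 3 and 0 of 4 libraries, and 6 were called in none. The other members, Ezh2 and Jarid2, named after their values were seen, leaned the other way at 0 of 3 and 1 of 4. PRC1 and MBT-domain genes were called at 1.15% ± 1.99 and 5.17% ± 4.45 (SD), with Phc1 in 0 of 3 and 2 of 4 and Rnf2 in 0 of 3 and 1 of 4, and differed by 2.299 points without knockout library 4. None of the 39 Hox genes, the classical targets of Polycomb silencing, had an end peak in any library.

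Cell cycle genes were called at 12.3% ± 8.04 and 13.2% ± 16.4 (SD), with Pcna in 2 of 3 and 2 of 4, and Wnt pathway genes at 7.69% in every wild-type library and 9.62% ± 9.68 in knockout libraries (SD), with Gsk3b in 3 of 3 and 3 of 4. Without knockout library 4 the differences were −7.02 and −2.56 points, and they were −2.22 for ventral telencephalon and −8.89 for housekeeping genes. Ventral telencephalon and interneuron genes, markers of cells outside the dorsal progenitor pool, were called at 8.89% ± 7.70 and 10% ± 6.67 (SD), close to the share of all protein-coding genes, with Gad2 and Gsx1 in 2 of 3 and 2 of 4 and Isl1 in 0 of 3 and 2 of 4. Meningeal genes were called at 0% and 5% ± 5.77 (SD), from Dcn in 2 of 4 knockout libraries, and no glial, endothelial or microglial and blood gene was called in any library. Housekeeping genes stood at 15.6% ± 3.85 and 16.7% ± 20.7 (SD), and all protein-coding genes at 8.39% ± 2.41 and 9.11% ± 6.30 (SD). In the exact permutation test 0 of the 16 lists passed, 0 had an unadjusted p under 0.05, and every adjusted p was 1. The smallest adjusted p that a single list could reach alone was 0.457, so this test could hardly have passed one.

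In the wider loci, the gene span and 50 kb on either side, radial glia and Hox genes stood apart from random lists and the other 14 lists did not. At gene ends the radial glia list did not stand apart, with a ratio of 0.860 (random-list permutation p = 0.944, adjusted p = 0.964), while Hox genes, with no calls, did (random-list permutation p = 0.0004, adjusted p = 0.0064). In the wider loci, radial glia and neural stem cell loci held 1.12 peaks per gene and library against 0.465 in random lists matched on gene length, a ratio of 2.41 (random-list permutation p = 0.0032, adjusted p = 0.0256). Excitatory neuron loci had a ratio of 1.88 that did not pass the adjustment (random-list permutation p = 0.0262, adjusted p = 0.140). Hox loci held 0.0366 peaks per gene against 0.361, a ratio of 0.102 (random-list permutation p = 0.0002, the smallest the 10000 lists can give, adjusted p = 0.0032), although these genes lie in clusters and are not independent. Without wild-type library 1 the Hox ratio was 0.0343 with the same adjusted p. The radial glia ratio stayed between 2.36 and 2.46 without each library, but its adjusted p was 0.0528 without knockout library 4. With equal lists the ratio was 2.54 with an adjusted p of 0.0912, and at −log10 q of at least 5, with 0.1 peaks per gene, it was 2.47 with 0.577, where that of the Hox loci was 0.240. A further alternative left out of each list the member with most peaks. Radial glia without Gli3 then had a ratio of 2.15 (random-list permutation, adjusted p = 0.0112). The meningeal list without Dcn then also passed, at a ratio of 0.149 (random-list permutation, adjusted p = 0.0235), so which lists stand apart depends in part on single members.

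Individual loci, chosen after their values were seen, showed where these peaks lay. Gli3 held 5 ± 1 peaks in wild-type and 6.25 ± 5.19 in knockout libraries, where library 4 had 14 and the other 3 averaged 3.67 ± 0.577. Vim, an intermediate filament gene of radial glia, held 2 ± 1 and 1.5 ± 0.577 (SD, n = 3 and 4). Sox9 and Tbr1 each had 1 peak in every library, and Hes1 and Eomes had none in any. A region inside Pax6 (chromosome 2, 105686825 to 105687037) was called in 3 of 3 wild-type and 2 of 4 knockout libraries, and a region beyond it (105719917 to 105720216) in 0 of 3 and 3 of 4. In the latter, the peaks of knockout libraries 1 and 2 did not overlap and were joined by that of knockout library 4. A region beside Fezf2 (chromosome 14, 12393286 to 12393862) was called in 1 of 3 and 4 of 4. Peaks per gene passed the test between genotypes in 0 of the 16 lists, with proneural loci at 0.578 ± 0.214 and 0.950 ± 0.585 and radial glia loci at 0.933 ± 0.252 and 1.26 ± 0.937 (SD, n = 3 and 4, exact permutation p = 0.371 and 0.886, every adjusted p = 1). Without knockout library 4 the knockout means were 0.667 ± 0.176 and 0.80 ± 0.180, so that the radial glia value turned below that of wild-type.

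**Figure D4:**
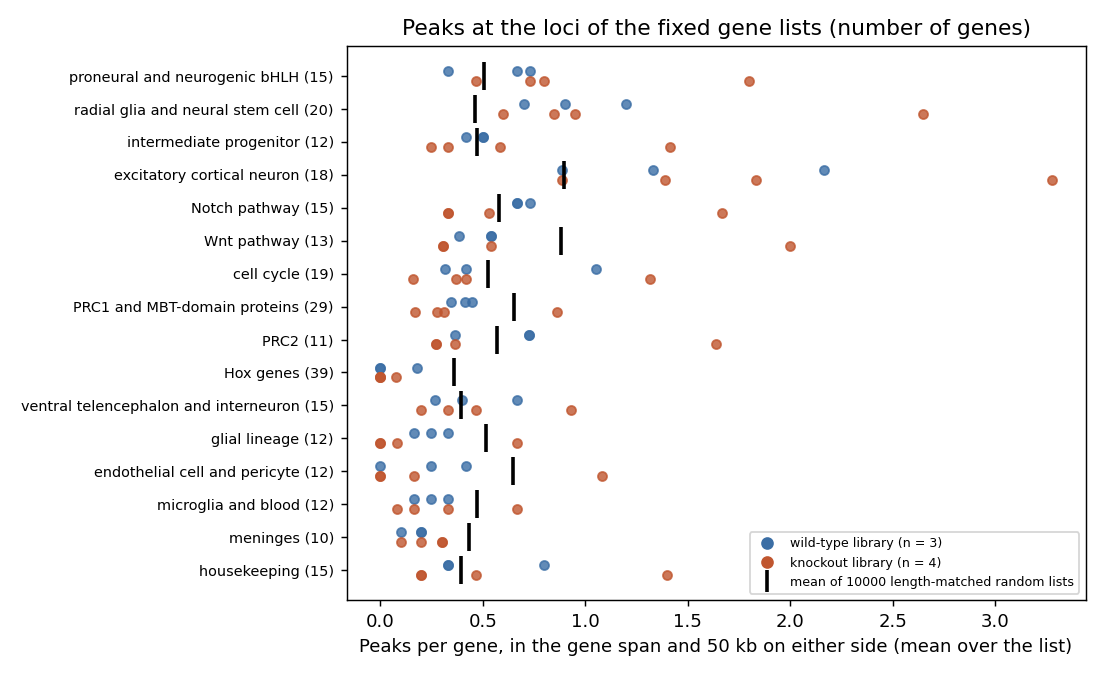
Peaks per gene in the gene span and 50 kb on either side for the 16 gene lists (number of genes in brackets), with 1 point per wild-type (blue) or knockout (orange) library and a vertical line at the mean of 10000 length-matched random lists. Radial glia libraries lie above their line of 0.465 and Hox libraries below theirs of 0.361, and knockout library 4, which has the longest list, is the farthest right in most lists.

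The last comparison asks whether libraries of 1 genotype shared more open regions with each other than with the other genotype. The same sites led every list, among them a site inside the neural adhesion gene Chl1 (chromosome 6, 103649049 to 103649291), with the authors' fold enrichment between 40.8 and 43.1. No filter for sites of artificially high signal was applied here, so whether these leading sites are open chromatin was not tested. The mean Jaccard index was 0.268 between wild-type libraries (3 pairs), 0.229 between knockout libraries (6 pairs) and 0.260 between libraries of different genotype (12 pairs). This index is lowered where lists differ in length. Knockout libraries 3 and 4, the shortest and longest lists, had the lowest index of any pair, 0.121. They also shared the highest percentage of the shorter list, 83.9%, so the means do not rank the groups by sharing. Overlap within genotypes minus overlap between them was −0.0177, and 31 of the 35 splits gave a difference at least as high (one-sided permutation p = 0.886).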

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

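The comparison of region counts with other splits was planned, but what it should show under chance was written after the counts were seen. The test of linkage to L3mbtl3 was chosen after the counts or positions were seen. In 3 of 22 groups tested, 1 knockout library stood far from the other 3. Chance gives about 1 in 20 for continuous values, a rate that does not apply here, since the other 3 libraries were tied in each case and any different value would have stood apart. Knockout library 4 had end peaks at 16.7% of intermediate progenitor genes (others 0%), at 18.2% of PRC2 genes (others 0%) and at 20% of ventral telencephalon and interneuron genes (others 6.67%). This library has the longest list, 17362 peaks. With lists of equal length it was above the other knockout libraries in 0 of the 3 gene lists, but in 2 of these all 4 knockout libraries were then at 0, so that the test cannot decide. List length is a candidate explanation and stays open, as does an effect of genotype in part of the libraries.

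The regions separating the genotypes, 34 called in wild-type and 28 in knockout libraries only, are the pattern a reader would most want to follow up. Of the 35 splits, 20 gave as many in the group of 3 (highest other 446) and 17 as many in the group of 4 (highest other 349), so chance cannot be excluded. The splits with the highest counts group libraries by list length, such as wild-type 2 with knockout 1 and 4. Ratios to the count expected from calling odds were 1.14 and 1.26. At least as high a ratio came from 15 of the 35 splits in the group of 3 (highest other 2.35) and from 5 in the group of 4 (highest other 3.04). The ratios thus lay inside the range of the other splits, the result predicted for list length. Simulated mean ratios for 50 changed regions per direction also lay below these highest values, so this outcome cannot tell list length from an effect of genotype. DNA linked to L3mbtl3 from another strain may also separate genotypes. Of the 62 regions, 1.61% lay within 20 Mb of the gene against 2.06% of other regions called in 3 or 4 libraries (one-sided Fisher exact p = 0.727). With 1.28 regions expected in the window, this test could hardly show an excess. Linkage within 20 Mb cannot account for the 61 regions outside it, and longer or unlinked segments were not tested. An effect of the L3mbtl3 genotype on part of these regions stays open. Simulated sets of 50 changed regions per direction ranked first in only 10 and 11 of 20 runs. Their mean ratios, 1.89 ± 0.148 and 2.17 ± 0.292 (SD), lay above the observed 1.14 and 1.26. Ratios of the other splits of these lists ran from 0.469 to 2.35 and from 0 to 3.04, wider than the simulated spread. The simulation therefore cannot decide whether 50 regions per direction changed. Fewer changed regions, or calling that differs between libraries, were not simulated.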

How the results depend on the processing

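The fits against random lists, and their alternatives, and the counts without the shortest and longest lists and the locus peaks without knockout library 4 were chosen after seeing the data. The share of peaks at gene ends and the overlap difference kept their sign under every alternative run, but not their size. Without single libraries the share ranged from −1.25 to −0.0998 percentage points and the overlap difference from −0.0383 to −0.00656. In every alternative that tested the gene lists, 0 of the 16 passed. That says nothing on stability, since 1 list alone cannot go below an adjusted p of 0.457. The peak number difference ranged from −1665 to 3000 without single libraries, covered length from −334 to 669 kb, and genes with an end peak from −492 to 561.7, with −13.3 for genes with equal lists. Separated regions ranged from 38 to 199 in wild-type and from 35 to 208 in knockout libraries without single libraries. They numbered 1 and 2 at −log10 q of at least 5, a filter that left 140 to 1771 peaks per library. Mean −log10 q percentiles of the regions found with all peaks were at most 74.5 in wild-type and 77.3 in knockout. Such regions could hardly stay called in every library under this filter, whatever their cause. With equal lists, which also drop lower-ranked peaks, they numbered 25 and 16. The counts were 186 and 152 with at most 1 library of the other genotype allowed. Without the shortest and longest lists, where fewer libraries have to be passed, they were 155 and 373. Same-numbered libraries had deviations correlated at 0.00132, 0.0716 and 0.0760, and differently numbered libraries at −0.103 to 0.0851. These values do not settle whether the replicate numbers pair the libraries. With the replicate block, over 3 pairs with a smallest p of 0.25, the differences were −1665 peaks, −334 kb and −492 genes (each exact p = 0.5), with 132 regions in wild-type only, and no call changed. Of 224 list values, 122 kept their sign, 24 reversed, 22 became 0, 8 left 0 and 48 were 0 in both. An unadjusted 0.05 was passed by 1, PRC2 minus the share of all genes, at −11.3 points (exact p = 0.0286, adjusted p = 0.457). In percentage points of knockout minus wild-type, reversed lists at −log10 q of at least 5 were housekeeping at −0.556, and with equal lists intermediate progenitor at −2.78, excitatory neuron at −0.463, ventral telencephalon at −5 and housekeeping at −1.67. Windows of 2.5 kb gave −2.22 for proneural and −4.17 for intermediate progenitor genes, and loci with 50 kb gave −4.44 for Notch, −2.63 for cell cycle, −3.45 for PRC1 and MBT-domain, −1.67 for meninges and −3.89 for housekeeping. Without single libraries the ranges were −2.78 to 4.17 for intermediate progenitor, −2.56 to 5.13 for Wnt, −7.02 to 5.26 for cell cycle, −3.33 to 3.33 for ventral telencephalon and −8.89 to 6.67 for housekeeping genes. The block gave −2.78, −2.56, −7.02, −2.22 and −8.89 for these 5. Hpf1 and Trmt9b reversed to 25 points at −log10 q of at least 5. Apart from the changes set by fewer libraries or peaks, the cause was not tested. Alternatives for E-box density, exon and intron shares and transcript starts, equal lists for the peak number and a paired overlap were not run. Unknown read depth limits every statement that a region was not called.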

Other observations

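The gene families were chosen after the values were seen, and their members often lie in clusters, so the random lists treat them as more independent than they are. Zfp zinc-finger genes, a large family of transcription factors, carried end peaks often, with 171 of 397 genes called in at least 1 library and 1.99 times the calls of length-matched random lists (random-list permutation p = 0.0002, the smallest the lists can give). Genes for cytosolic ribosomal proteins had a ratio of 2.74 (42 of 97 called) and NADH dehydrogenase subunit genes of the respiratory chain a ratio of 2.14 (23 of 49 called). Mitochondrial ribosomal protein genes had a ratio of 1.57 and proteasome genes of 1.27, and neither passed (random-list permutation p = 0.0598 and 0.403).

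Sensory and epithelial families were almost without end peaks. Of 1110 Olfr olfactory receptor genes 1 was called, of 355 Vmn vomeronasal receptor genes 3, and of 53 keratin genes 0. Potassium channel genes, which serve mature neurons among other cells, had a ratio of 0.410 (14 of 94 called, random-list permutation p = 0.0036). Between genotypes 0 of the 9 families passed the test, with Zfp genes called at 20.6% ± 7.22 in wild-type and 19.5% ± 11.99 in knockout libraries (SD, n = 3 and 4, exact permutation p = 0.857, adjusted p = 1).

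The site with the highest −log10 q was the same in all 7 lists, at chromosome 2, 98666240 to 98667320, 1035 kb from the nearest protein-coding gene, Lrrc4c. Its fold enrichment by the authors was 10.1 to 11.4, below that of the site near Abcb11 (chromosome 2, 69355538 to 69355665), at 49.2 to 53.1, which ranked 3 or 4. Without a filter for sites of artificially high signal, whether either site is open chromatin was not tested.

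One hypothesis was that regions called in a single library follow chromosomes with few genes while shared regions follow chromosomes with many. Across 20 chromosomes, regions per Mb called in 1 library had a Pearson r of −0.0632 with genes per Mb (permutation p = 0.793, Spearman rho −0.0677, permutation p = 0.778). Regions called in all 7 libraries had r = −0.410 (permutation p = 0.0732, adjusted p = 0.293 over 4 relations, rho = −0.368, permutation p = 0.1098), and −0.136 without the 2 chromosomes farthest from the median, so neither relation could be established and these data leave the hypothesis undecided.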
